A study of Mus musculus with 80 samples.

How the data were processed

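Liver RNA of 16 DEHP and 24 DCA animals was sequenced from frozen tissue and from FFPE tissue of the same animals, giving 80 libraries made with a stranded total RNA kit that depletes ribosomal RNA, from 100 ng of RNA (4 sections of 10 µm for FFPE). Per the submitters' processing notes, reads were called with CASAVA, aligned with STAR 2.4 and quantified with RSEM against mm10. The deposited gene tables of the main fits hold expected counts that the authors made with RSEM, not normalised, for 18877 genes (DEHP) and 17672 genes (DCA). They were rounded to whole numbers. All columns were matched to libraries by the animal, preparation and dose in their names. A second set of deposited raw count tables served as an alternative. Its DEHP table lacked frozen library 40A (31 libraries), and its DCA FFPE table ended after 19008 complete genes. The RPKM and FPKM tables of the authors were not used here.

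Each chemical and preparation was fitted separately in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with its 4 dose groups, filterByExpr (minimum count 10), TMM scaling and the quasi-likelihood test. Each dose was compared with 0, and a slope on dose was tested. Calls are Benjamini-Hochberg adjusted p values under 0.05 over all genes tested, from edgeR and 2-sided throughout, and list calls are from camera in limma. The SE of a log2 fold change is its size divided by the square root of the F statistic. Frozen and FFPE libraries were compared as paired samples with the animal as replicate block, and the same block was used to test whether the top-dose effect differed between preparations. The top-dose effects of the chemicals were compared in 1 joint fit of the frozen libraries, each against its own controls. A benchmark dose was the dose at which a line of log2 CPM on dose moved by 1 residual SD (2 as an alternative). It was taken over genes with a trend, the same sign and a benchmark dose below the top dose in both preparations. Values given as CPM are scaled with TMM.

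Genes were named by a rule. It took the 6 largest rises and falls per chemical in frozen liver (4 in FFPE) among called genes with a mean log2 CPM of at least 2 whose top-dose libraries all lay beyond every control. It added the 2 called members of smallest adjusted p of each list, and always a fixed set of genes, among them Cyp4a10, Cyp4a14, Ehhadh, Acot1, Pdk4, Cyp2b10, Cyp3a11, Cyp2c55, Gstz1, Cyp7a1 and Alb. Predicted-gene and clone symbols were passed over, and this was extended to names of GenBank clone accessions after the data were seen. List members outside the rule are named without values. Unless stated otherwise, all treated libraries of a named gene lay beyond every control.

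The 35 gene lists covered peroxisomal, Cyp4 and mitochondrial fatty acid oxidation, other PPAR alpha markers, CAR and PXR, NRF2, AhR and p53 targets, cholesterol and fatty acid synthesis, glucose and glycogen, pyruvate dehydrogenase, tyrosine and bile acid metabolism, cell cycle, acute phase, male- and female-biased genes, the clock, unfolded protein, heat shock, immediate early and interferon responses, and markers of pericentral, periportal and secreting hepatocytes, Kupffer cells, endothelium, stellate cells, bile duct, lymphocytes, red blood cells, exocrine pancreas, skeletal muscle and the mitochondrial genome. Lists with at least 3 tested members were tested with camera (preset correlation 0.01), and again with an estimated correlation and with fry. The design, lists, naming rule and most alternatives were set before the data were examined.

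The alternatives were DESeq2 1.42.0, its size factors in edgeR, upper-quartile factors, no or a stricter filter (1 CPM and 10 counts), the other tables, thinning to the smallest total, a fold change of at least 2, an adjusted p under 0.01, fits of the compared groups only, no replicate block, and leaving out each library. Sequencing run as a term, removal of the Rn45s row, fits without selected libraries or within 1 run, DESeq2 size factors for the fold changes compared between preparations, and leaving out animals in turn for DEHP FFPE against frozen, its differing effects and DEHP against DCA were chosen after seeing the data. Upper-quartile factors were not run for DCA FFPE because 1 library has an upper quartile of 0.

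Pairing was checked by correlating frozen and FFPE residuals of animals within a dose. Of 16 DEHP animals 14 matched their own partner best (median r 0.582 over 7776 genes), and of 24 DCA animals 13 did (median r 0.0500 over 4711 genes). The DEHP animals that did not were 35A (r 0.066) and 67C (r 0.081), both at 3000 ppm. They were kept as labelled in the paired fits, and whether their labels are right was not tested. The fits were tested on data simulated with the real depths and the spread within groups, without an animal effect shared between preparations. At the top dose, 86% of 2-fold changes were recovered in DEHP frozen, 72% in DEHP FFPE and 97% in DCA frozen, with 8 to 10 false calls. In DCA FFPE none of 65 genes changed 2-fold and 2 of 68 changed 4-fold were recovered. The test of a difference between preparations recovered 47% of 2-fold and 94% of 4-fold differences for DEHP, and none of 100 for DCA at either size. Since the simulated pairs shared no animal effect, recovery by the paired tests may differ in the real pairs. Folds against a group with 0 counts are bounds set by a floor of 3 counts over the group, and counting intervals are at 95%. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.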

Results

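RNA was sequenced from livers of male B6C3F1 mice, a hybrid strain used in chemical safety studies, after exposure to 1 of 2 chemicals. Di(2-ethylhexyl) phthalate (DEHP), a plasticizer, was given in feed for 7 days at 0, 1500, 3000 or 6000 ppm to 16 mice, 4 per dose, and the livers were collected in 2013. Dichloroacetic acid (DCA), a by-product of water chlorination that inhibits pyruvate dehydrogenase kinase, was given in drinking water at 0, 1, 2 or 3.5 g/L to 24 mice, 6 per dose, and these livers were collected in 1994. The labels do not give the length of the DCA exposure. Each liver gave 1 library from frozen tissue of mixed lobes and 1 library from formalin-fixed, paraffin-embedded (FFPE) tissue of specific lobes, 80 libraries in all. The pairs address whether fixed tissue, recent or stored for years, shows the dose responses seen in frozen tissue.

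The frozen and FFPE libraries of the DEHP animals and the frozen libraries of the DCA animals were deep, while the FFPE libraries of the DCA animals were shallow. The median total count was 22009499 in DEHP frozen libraries (16582951 to 29550616), 16405450 in DEHP FFPE (11673034 to 18866106), 14686415 in DCA frozen (3067666 to 16890024) and 504138.5 in DCA FFPE (109292 to 8434613). Rn45s, the ribosomal RNA precursor that the library kit is meant to deplete, took a median of 0.140%, 2.90%, 0.449% and 56.5% of the counts in these 4 sets. Rows named by GenBank clone accessions took a median of 7.83%, 24.6%, 11.99% and 7.78% in the same order. In every DEHP FFPE library the largest row was such a row, with a median of 15.3% of the counts. What RNA these rows hold was not tested. In the DCA FFPE set all 6 controls and 3 libraries at 1 g/L came from sequencing run V18431 and had 1385869 to 8434613 counts. The other 3 libraries at 1 g/L and all libraries at 2 and 3.5 g/L came from run W48315 and had 109292 to 653006 counts, so that run, depth and dose cannot be told apart at 2 and 3.5 g/L. In the DCA frozen set all controls were sequenced in lane L5 and all libraries at 3.5 g/L in lane L4 of run W48315, so lane and dose cannot be told apart there either. The DEHP frozen controls came from runs H36399 and H36451. Of the treated DEHP frozen libraries only 72B, 35A and 8C were in these runs, so run and dose were largely confounded there.

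**Figure D1:**
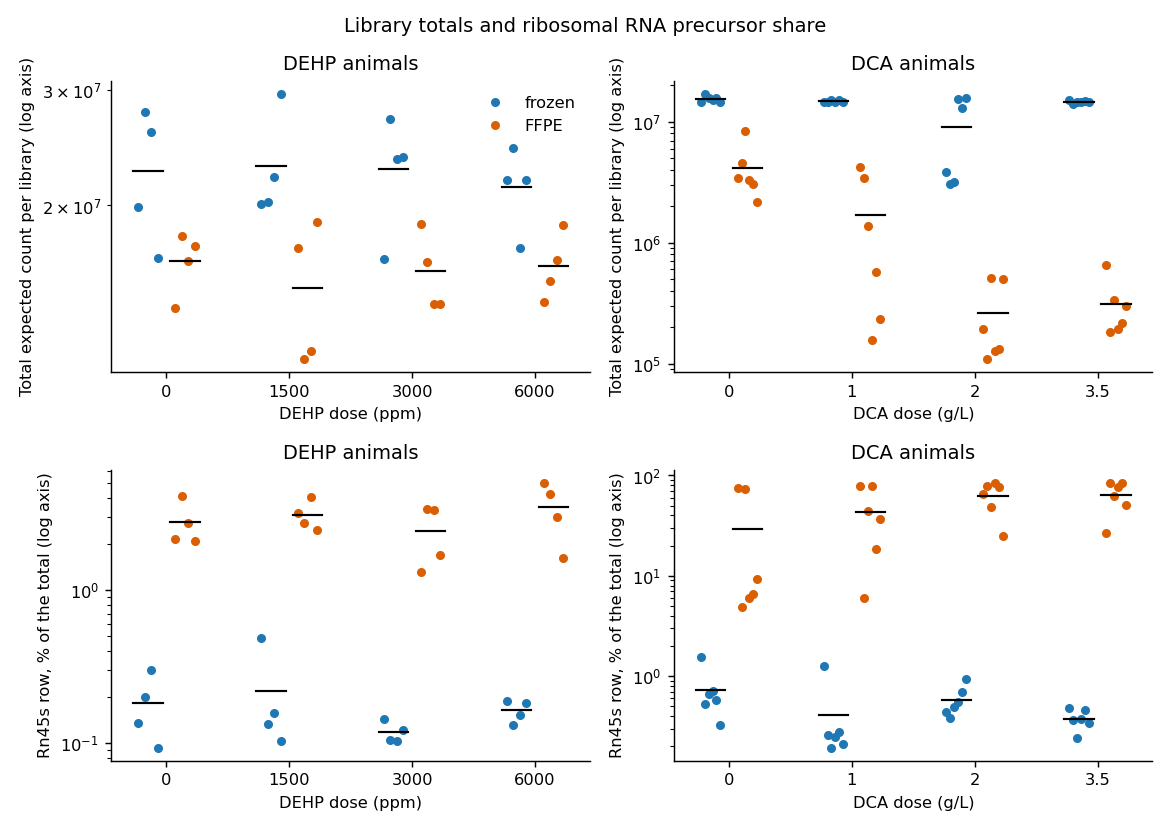
Total counts per library and percent of counts in the Rn45s row (log axes) by dose, for DEHP (ppm) and DCA (g/L), with 1 point per library and frozen and FFPE libraries in separate colours. FFPE libraries of the DCA animals at 2 and 3.5 g/L had 109292 to 653006 counts, below every other group of libraries apart from 3 at 1 g/L.

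In frozen liver of the DEHP animals, genes of fatty acid oxidation and drug-metabolising cytochrome P450 genes were among those raised at 6000 ppm. Cyp4a14, a fatty acid omega-hydroxylase (mm10 chromosome 4, 115486200 to 115496142, minus strand, protein coding), rose by 7.61 ± 1.05 (log2 fold change and SE, n = 4 per group), to 7623 ± 2337 CPM (TMM-scaled, mean and SD). Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation (chromosome 16, 21761287 to 21787807, minus strand, protein coding), went from 207 ± 183 to 11260 ± 4652 CPM (log2 5.77 ± 0.51). Cyp2b10, a cytochrome P450 induced through the receptor CAR (chromosome 7, 25897620 to 25926624, plus strand, protein coding), was at 3 counts over all controls and rose 212-fold (95% counting interval 72.2 to 1030). Among falls, Serpina12, which encodes the adipokine vaspin (chromosome 12, 104028769 to 104044443, minus strand, protein coding), fell by 4.08 ± 0.73 on the log2 scale. Adjusted p values of these 4 genes were 1.79e-04, 4.47e-06, 2.64e-05 and 0.00158, and for each gene all 4 treated libraries lay beyond every control.

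The peroxisomal fatty acid oxidation list rose in 17 of 20 tested members, with none lower. In this and the next 3 paragraphs, numbers in parentheses after a count of members are the rises and falls adjusted over the list alone (here 18 and 0). Acot3, a peroxisomal thioesterase, rose by 5.87 ± 0.92 (log2). Mitochondrial fatty acid oxidation and ketogenesis genes rose in 20 of 23 members with none lower (22 and 0), among them Acot2 (log2 7.00 ± 0.59), Acot1 (5.85 ± 0.86) and Eci1 (1.97 ± 0.20), which shifts double bonds in fatty acids. Other PPAR alpha markers rose in 19 of 23 members with none lower (19 and 1), including the fatty acid transporter Cd36 (4.52 ± 0.38) and the fatty aldehyde dehydrogenase Aldh3a2 (3.98 ± 0.38). CAR and PXR targets rose in 12 of 20 members with none lower (12 and 2), including Cyp3a11 (4.09 ± 0.55) and Cyp2c29 (1.91 ± 0.22). These 4 lists passed camera with medians of 1.65, 1.21, 1.56 and 1.10 log2, and their adjusted p was 0.0431, 0.0431, 0.0498 and 0.0445 with an estimated correlation. The Cyp4 omega-hydroxylation list rose in 7 of 10 members and fell in 2 (7 and 3), the falls being Cyp4f14 and Cyp4v3, and its adjusted p was 0.168 with an estimated correlation. How reads were shared between the near-identical Acot1 to Acot4 genes, and among the Cyp4a, Cyp2a and Cyp2b genes, is uncertain.

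Some genes of cell division, cholesterol synthesis and antioxidant defence also rose at 6000 ppm. Cell cycle genes rose in 15 of 24 members with none lower (18 and 0; median 1.73 log2, adjusted p = 0.218 with an estimated correlation). Their 2 members of smallest p, the replication helicase gene Mcm4 (0.92 ± 0.18) and the mitotic cyclin Ccnb1 (3.55 ± 0.75), lost their calls with sequencing run as a term (adjusted p = 0.0744 and 0.135). Cholesterol synthesis genes rose in 11 of 23 members with none lower (13 and 0; median 0.69, adjusted p = 0.218 with an estimated correlation), including Hmgcs1 (1.77 ± 0.33) and Nsdhl (1.05 ± 0.19). NRF2 targets rose in 7 of 18 members and fell in 1 (10 and 2; adjusted p = 0.218 with an estimated correlation), with Ephx1 (2.00 ± 0.22), an epoxide hydrolase, and Srxn1 (1.67 ± 0.30), a peroxiredoxin reductase, among the rises. Fatty acid and triglyceride synthesis rose in 8 of 19 and fell in 2 (8 and 2; adjusted p = 0.509 with an estimated correlation, 0.159 without control 75A and 0.0803 without 8C), with the malic enzyme Me1 up and Pklr, a glycolytic kinase, down (-1.83 ± 0.28). Of 13 female-biased liver genes 4 were tested, since the filter drops genes with few counts in every group. A gene near 0 in controls thus enters mainly if treatment raises it, so the share that rose is no evidence by itself. All 4 rose (4 and 0, median 5.54, adjusted p = 0.0647 with an estimated correlation). These were Cyp2b9, Cyp2a4, Cyp3a44 and Cyp17a1. In the controls Cyp2b9 and Cyp2a4 were at 3 counts each, with rises of 607-fold (207 to 2944) and 327-fold (112 to 1587) by counting interval. Cyp2b9 and Cyp3a44 are also among the CAR and PXR targets above. Pyruvate dehydrogenase and pyruvate import genes rose in 2 of 14 with none lower (4 and 0; adjusted p = 0.218 with an estimated correlation), including the kinase Pdk4 (2.74 ± 0.57, 3 of 4 libraries above all controls). Heat shock genes rose in 3 of 10 with none lower (4 and 0; adjusted p = 0.509 with an estimated correlation, 0.160 with run as a term, 0.201 without control 32A, 0.159 without control 75A and 0.0811 without 8C), and the mitochondrial chaperone Hspd1 rose by 0.88 ± 0.15.

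Some genes of hepatocyte secretion, bile acid handling and the periportal zone fell. The acute phase list fell in 7 of 18 members with none higher (0 and 8; median -0.84, adjusted p = 0.444 with an estimated correlation), including the protease inhibitor Serpina3m (-1.71 ± 0.25), 1 of a family of similar genes. Hepatocyte secreted protein genes fell in 5 of 10 (1 and 8; adjusted p = 0.194 with an estimated correlation), including Ahsg (-1.02 ± 0.15), which encodes fetuin A. Periportal genes fell in 4 of 10 (0 and 4; adjusted p = 0.168 with an estimated correlation), including the urea cycle enzyme Cps1 (-0.91 ± 0.15) and the glutaminase Gls2 (-0.91 ± 0.16). Bile acid synthesis and transport fell in 7 of 15 and rose in 1, the phospholipid exporter Abcb4 (1 and 10; adjusted p = 0.218 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275633, minus strand, protein coding), had a log2 fold change of -1.66 ± 0.47 (adjusted p = 0.0279, 4 of 4 below all controls). That call was lost with run as a term (adjusted p = 0.236) and without control 63A (0.0580), control 75A (0.0733), 44A (0.0908), 64C (0.0658) or 8C (0.0897). Male-biased genes fell in 5 of 10 and rose in 2 (2 and 6; adjusted p = 0.352 with an estimated correlation and 0.160 without control 32A), the major urinary protein Mup21 being lower by -2.87 ± 0.38 and the Cyp4a12 pair higher. The unfolded protein response list fell in 2 of 16 (0 and 6; adjusted p = 0.509 with an estimated correlation and 0.121 without control 45C).

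Markers of the other liver cell types were not called as lists in frozen liver at 6000 ppm, although the Kupffer cell list was called upward without control 75A (adjusted p = 0.00933), 64C (0.0364) or 8C (0.00844). No member passed among 11 Kupffer cell, 4 bile duct, 3 lymphocyte and 4 red blood cell genes, and 1 passed among 10 endothelial genes (Oit3) and among 11 stellate cell genes (Col3a1). Camera likewise did not call the AhR target (1 of 6 members higher), glucose and glycogen (3 higher and 5 lower of 20), tyrosine catabolism (none of 5), circadian clock (1 lower of 15), immediate early (none of 10), p53 target (2 higher of 14; adjusted p = 0.0434 without control 45C), interferon (none of 17) or pericentral (none of 10) lists. In the immediate early list the median was -0.10, the mean 0.01 and the direction of the test upward. Adjusted over the list alone the glucose list had 3 rises and 6 falls, the stellate list 2 and 2, and the red blood cell list 0 and 1. Of the exocrine pancreas genes 1 was tested, the elastase Cela1, and it was lower. Albumin (Alb, chromosome 5, 90460897 to 90476602, plus strand, protein coding) was at 45880 ± 6317 CPM in controls and 40600 ± 5817 CPM at 6000 ppm (log2 -0.18 ± 0.16, adjusted p = 0.546, 1 of 4 libraries below all controls).

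By count, 1625 of 13802 tested genes changed at 6000 ppm in frozen liver (973 up, 652 down), against 2022 at 3000 ppm (1127 up, 895 down) and 895 at 1500 ppm (599 up, 296 down). At 1500 ppm Cyp4a14 was already at 4281 ± 344 CPM and Ehhadh at 5180 ± 615 CPM, while Cyp2b10 went from 0.545 ± 0.518 to 0.805 ± 0.129 and 6.96 ± 2.60 CPM over the 3 doses. A linear trend with dose passed in 360 genes (196 up, 164 down). With run as a term the counts were 391, 561 and 667 genes at 1500, 3000 and 6000 ppm. Few treated libraries shared a run with a control, so this fit cannot cleanly separate run from dose. The count at 1500 ppm was 468, 480 and 493 without controls 45C, 63A and 75A, 494 without 40A and 445 without 60A. At 3000 ppm it was 1246 without control 63A, 1327 without 67C and 1322 without 9A, and at 6000 ppm 1079 without control 63A, 921 without 44A and 903 without 8C. The trend count was unstable, at 119, 159, 110 and 163 without controls 32A, 45C, 63A and 75A, and 1266, 57, 232 and 105 without 29B, 44A, 64C and 8C.

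FFPE liver of the DEHP animals showed the same leading genes as frozen liver. At 6000 ppm Cyp4a14 rose by 7.15 ± 0.83 (log2), Ehhadh by 5.60 ± 0.51 and Cyp3a11 by 4.18 ± 0.58, and Serpina12 fell by 4.19 ± 0.69, with all 4 treated libraries beyond every control. Cyp2b10 had 0 counts in all FFPE controls and was at least 152-fold higher at 6000 ppm (3 counts over the group as floor). Cyp2b9 and the acyltransferase Mogat1, at 1 and 2 control counts, rose 1733-fold (311 to 68480) and 315-fold (86.8 to 2607). Peroxisomal genes rose in 17 of 20 members (18 adjusted over the list alone), mitochondrial fatty acid oxidation genes in 21 of 23 (22) and cholesterol synthesis genes in 13 of 23 (13). Camera called 17 of 31 lists (13 up, 4 down). The peroxisomal, mitochondrial, other PPAR alpha and CAR and PXR lists held (adjusted p = 0.0251 to 0.0349 with an estimated correlation), and for the other 13 lists the adjusted p was 0.0720 to 0.624 with an estimated correlation. These included the Kupffer cell list, in which no member passed and the median was 0.58 log2, and whose call was lost without control 32A (adjusted p = 0.171), control 45C (0.0758), 29B (0.123) or 44A (0.149). Some other divisions of the libraries called as many lists or more, so that chance is not excluded for the number of lists called.

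By count, 1680 of 13581 genes changed in FFPE at 6000 ppm (1078 up, 602 down), 1275 at 3000 ppm and 796 at 1500 ppm, and a dose trend passed in 487. At 6000 ppm the count was 856 without 44A and 1078 without 64C, and at 3000 ppm 846 without control 63A. At 1500 ppm it was 449, 458 and 423 without controls 45C, 63A and 75A, and 461, 367, 434 and 518 without 3A, 40A, 60A and 72B. The trend count was 117, 223, 119 and 210 without controls 32A, 45C, 63A and 75A, and 1028, 49 and 218 without 29B, 44A and 64C.

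Fold changes of the DEHP top dose in FFPE followed those in frozen liver of the same animals. Over the 1605 genes called in frozen liver and tested in both, the log2 fold changes had a Pearson r of 0.968 and a Spearman rho of 0.969 across genes that are not independent replicates. The sign was shared by 99.7% of them, and 69.9% were also called in FFPE. Both called up 754 genes, against 76.3 expected of independent lists, both called down 368 against 29.1, and none were called in opposite directions against 94.7, although the same animals gave both sets. Frozen and FFPE values were also taken from different animals, which left fewer animals at 0 and 6000 ppm in each fit. The median r over 36 divisions was then 0.878 (0.802 to 0.966). A median of 45.1% of the genes called in frozen liver were called the same way in FFPE (8.20 to 95.2). Whether the lower values came from fewer animals or from unshared animals was not separated. The test of a difference between the preparations in the effect of 6000 ppm found 0 of 14065 genes with edgeR (254 at an unadjusted p under 0.05). In data simulated without an animal effect shared between preparations, this test recovered 47% of 2-fold and 94% of 4-fold differences, so its recovery in the real pairs may differ. Over 249 genes with a dose trend in both preparations the median benchmark dose, at which the fitted line moved by 1 residual SD, was 1966 ppm in frozen and 2029 ppm in FFPE (median ratio 1.02, quartiles 0.912 and 1.13). A trend call needs a slope that is steep for its residual SD, so requiring it in both preparations bounds the benchmark dose in both. The near-equal medians thus follow in part from the selection of genes.

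**Figure D2:**
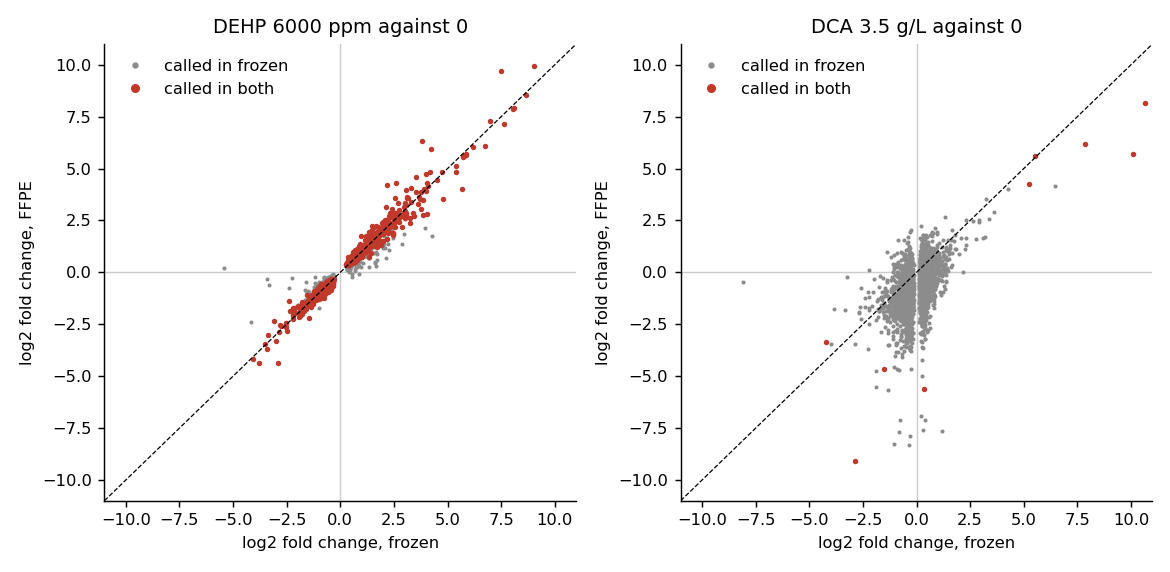
Log2 fold change of the top dose against 0 in frozen (horizontal axis) and FFPE liver (vertical axis), for DEHP at 6000 ppm and DCA at 3.5 g/L. Each point is 1 gene called in frozen liver and tested in both preparations, and other genes are not shown. The dashed line marks equal change and colours mark genes also called in FFPE. Across genes called in frozen liver r was 0.968 for DEHP and 0.511 for DCA.

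In frozen liver of the DCA animals at 3.5 g/L, 18 of 20 peroxisomal and 19 of 23 mitochondrial fatty acid oxidation genes and 9 of 19 fatty acid synthesis genes rose, while 16 of 18 acute phase, 15 of 17 interferon response and 9 of 11 Kupffer cell genes fell. Camera called 19 of 31 lists, and with an estimated correlation 0 of 31 (8 at an unadjusted p under 0.05, 23 with fry). Cyp4a14 went from 4.56 ± 4.58 to 5014 ± 1334 CPM (log2 10.08 ± 0.73, n = 6) and Ehhadh from 169 ± 25.5 to 6387 ± 1861 CPM (5.24 ± 0.36). Scd1, the desaturase of fatty acid synthesis, rose from 2200 ± 1307 to 20360 ± 1261 CPM (3.21 ± 0.30). Serpina1e, an alpha-1-antitrypsin gene, fell from 18160 ± 1188 CPM in controls (log2 -4.22 ± 0.33), and Nr1d1, a clock repressor (chromosome 11, 98767932 to 98775333, minus strand, protein coding), rose by 3.39 ± 0.21. All 6 treated libraries lay beyond every control for these genes, and the largest of their adjusted p values was 5.98e-09. Lrtm1 (-4.76 ± 0.25), the secreted peptide gene Tff3 (-4.63 ± 0.42) and Serpina12 (-4.51 ± 0.39) also fell.

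The peroxisomal list rose in 18 of 20 members and fell in 1, Scp2. As above, parentheses after a count of members give rises and falls adjusted over the list alone (18 and 1). Mitochondrial fatty acid oxidation rose in 19 of 23 with none lower (20 and 0), including Acadl (1.03 ± 0.07) and Decr1 (1.66 ± 0.12), and other PPAR alpha markers in 19 of 23 with none lower (20 and 0), including the lipid droplet protein Plin2 (2.29 ± 0.17). The adjusted p of these 3 lists was 0.0594, 0.0594 and 0.0865 with an estimated correlation. The Cyp4 list rose in 6 of 10 and fell in 3, Cyp4v3, Cyp4f14 and Cyp4f13 (6 and 3; adjusted p = 0.168 with an estimated correlation). NRF2 targets rose in 12 of 17 and fell in 1 (12 and 1; adjusted p = 0.0968 with an estimated correlation), including the glutathione transferase Gsta2 (2.85 ± 0.22) and Ephx1 (1.99 ± 0.16). Fatty acid and triglyceride synthesis rose in 9 of 19 and fell in 1 (9 and 1; adjusted p = 0.168 with an estimated correlation), including the elongase Elovl6 (2.24 ± 0.18), whereas cholesterol synthesis fell in 15 of 23 and rose in 3 (3 and 15; adjusted p = 0.324 with an estimated correlation), including Mvk (-1.61 ± 0.13) and Fdps (-0.98 ± 0.14) of the mevalonate pathway. Pyruvate dehydrogenase and pyruvate import genes rose in 9 of 14 and fell in 2 (9 and 2; adjusted p = 0.127 with an estimated correlation), including Pdk4 (3.24 ± 0.50), the phosphatase Pdp2 (0.97 ± 0.10) and Pdhb (0.67 ± 0.08). Gstz1, the enzyme that metabolises DCA (chromosome 12, 87147165 to 87164723, plus strand, protein coding), was at 423 ± 27.5 and 428 ± 15.5 CPM (log2 0.02 ± 0.06, adjusted p = 0.809, none of 6 above all controls).

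Many secreted protein and immune genes fell at 3.5 g/L. The acute phase list fell in 16 of 18 members (0 and 16; median -1.25, adjusted p = 0.264 with an estimated correlation), including Itih4 (-1.50 ± 0.19). Hepatocyte secreted genes fell in 8 of 10 and rose in 1, Apoa2 (1 and 8; adjusted p = 0.0976 with an estimated correlation), including transferrin, Trf (-1.31 ± 0.11), and albumin, which fell from 74040 ± 7556 to 54260 ± 6308 CPM (-0.45 ± 0.11, 5 of 6 below all controls). Interferon response genes fell in 15 of 17 (0 and 15; adjusted p = 0.168 with an estimated correlation), including the regulator Irf7 (-1.55 ± 0.18) and Oas1a (-1.19 ± 0.16). The unfolded protein response list fell in 10 of 16 and rose in 1, Atf3 (1 and 10; adjusted p = 0.276 with an estimated correlation), with Herpud1 down (-1.76 ± 0.23). Kupffer cell genes fell in 9 of 11 (0 and 11; median -0.65, adjusted p = 0.204 with an estimated correlation), including the complement genes C1qa (-0.96 ± 0.12) and C1qc. Endothelial genes fell in 4 of 10 (0 and 5; adjusted p = 0.227 with an estimated correlation, and 0.0705, 0.0556 and 0.0504 without controls 4, 7 and 8), including Stab1 (-0.42 ± 0.07), and red blood cell genes in 5 of 5 (0 and 5; adjusted p = 0.204 with an estimated correlation), including Alas2 (-1.24 ± 0.17), the haem enzyme of erythroid cells. Stellate cell genes fell in 7 of 11 (0 and 8) without a list call (camera adjusted p = 0.0570, and 0.0215, 0.0438 and 0.0448 without controls 3, 6 and 7, and 0.0455, 0.0459 and 0.0298 without 98, 99 and 101), and none of 5 bile duct genes passed. Haemoglobin genes took 0.0794% ± 0.0311 of frozen counts at 0 and 0.0397% ± 0.0138 at 3.5 g/L.

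Circadian, sex-biased and zonal genes moved as well. The clock list rose in 9 of 17 members and fell in 5 (9 and 5; adjusted p = 0.211 with an estimated correlation and 0.0504 without control 8): Nr1d1, Nr1d2 (2.30 ± 0.15), Dbp, Per3 and Clock were among the rises and Arntl, Npas2, Cry1, Nfil3 and Per1 the falls. Male-biased genes fell in 6 of 10 and rose in 1 (1 and 7; adjusted p = 0.168 with an estimated correlation), including Ugt2b38 (-3.34 ± 0.28) and the transporter Slco1a1 (-1.40 ± 0.14). Female-biased genes were not called as a list, with 3 of 7 higher and 1 lower (3 and 2), although Cyp2a4 rose by 7.12 ± 0.54 and Cyp2b9 by 6.25 ± 0.59. Pericentral genes fell in 6 of 10 (0 and 6; adjusted p = 0.111 with an estimated correlation), including Cyp1a2 (-1.38 ± 0.11) and the Wnt target Axin2 (-0.81 ± 0.12), and periportal genes in 6 of 10 with 1 rise (1 and 6), without a list call (adjusted p = 0.0495 without control 3 and 0.04995 without 98). Bile acid genes fell in 9 of 15 and rose in 2, Abcb4 and Cyp7a1 (1.35 ± 0.40, 4 of 6 above all controls; 2 and 9; adjusted p = 0.168 with an estimated correlation). Lists that camera did not call were CAR and PXR targets (8 higher and 6 lower of 21; 8 and 7), AhR targets (3 and 1 of 6; 3 and 1), glucose and glycogen (8 and 5 of 20; 8 and 5), tyrosine catabolism (1 and 1 of 5; 1 and 1), cell cycle (3 and 0 of 24; none over the list alone), heat shock (2 and 3 of 10; 2 and 3), immediate early (3 and 2 of 10; 5 and 2) and p53 targets (5 and 1 of 13; 5 and 1). The glycogen branching enzyme Gbe1 rose (1.39 ± 0.13). In the tyrosine list the median and mean were -0.07 and -0.01 with an upward test, and in the bile duct list 0.03 and 0.01 with a downward test. The exocrine pancreas list had 2 tested members, of which 1, Cela1, fell (-1.33 ± 0.17) and 1 had a call that was lost on leaving out any of several libraries. Of lymphocyte genes 1 was tested, and no gene of the skeletal muscle and mitochondrial genome lists could be tested.

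By count, 5631 of 13089 genes changed at 3.5 g/L (2868 up, 2763 down), 3822 at 2 g/L (2025 up, 1797 down) and 1455 at 1 g/L (538 up, 917 down), and 5141 passed the dose trend. With upper-quartile factors the 3.5 g/L count was split 2228 up and 3379 down. At 1 g/L Cyp4a14 was at 12.4 ± 9.85 CPM and not called (adjusted p = 0.0993, 3 of 6 above all controls), while Nr1d1 had already risen by 1.23 ± 0.21 (adjusted p = 6.22e-04, 6 of 6). Without 73, 74 and 75 the 2 g/L count was 2377 (1247 up, 1130 down). These 3 libraries (lane L3, 3067666 to 3854949 counts) had 6670 to 7524 CPM of Ehhadh, against 809 to 3988 CPM in 76, 77 and 78 (lane L4, 13120816 to 15660753 counts). The 1 g/L count was 510 with run as a term and 2317 without 49, 863 without control 3, 870 without 51, 960 without 52 and 899 without 54.

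**Figure D3:**
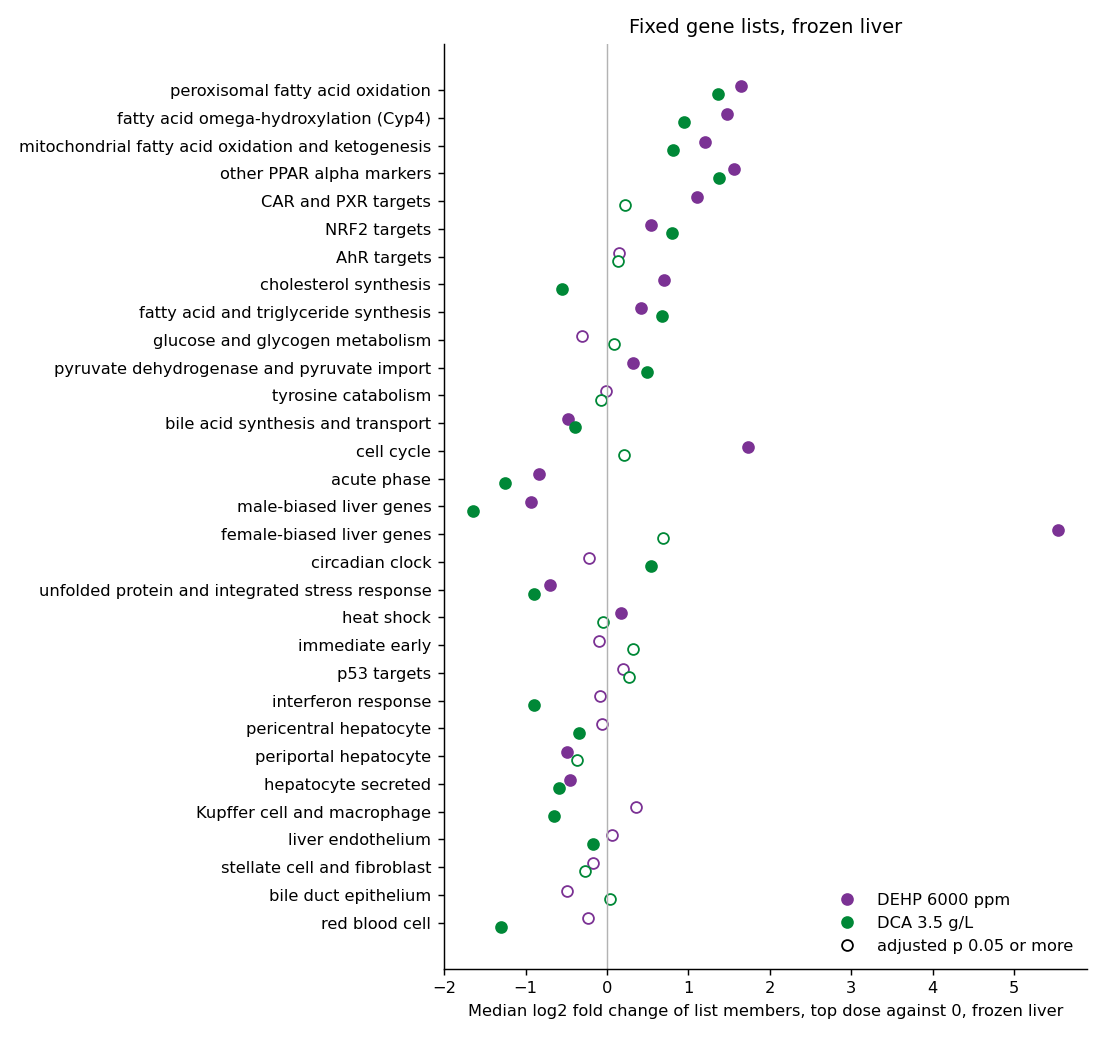
Median log2 fold change of list members at the top dose against 0 in frozen liver (horizontal axis), 1 line per list, for DEHP at 6000 ppm and DCA at 3.5 g/L, with open symbols where the camera adjusted p was 0.05 or more. The cholesterol synthesis median was 0.69 for DEHP and -0.55 for DCA.

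In FFPE liver of the DCA animals Cyp4a10, Cyp4a14 and Ehhadh rose at 3.5 g/L, and few other genes passed. Cyp4a10 rose from 11.1 ± 4.85 to 787 ± 590 CPM (log2 6.17 ± 0.81, adjusted p = 5.30e-11, n = 6), Cyp4a14 by 5.71 ± 0.76 (adjusted p = 8.94e-11) and Ehhadh by 4.26 ± 0.71, and Serpina1e fell by 3.34 ± 0.61, each in 6 of 6 libraries. With run as a term Ehhadh and Serpina1e were not called (adjusted p = 0.259 and 0.117). The glucocorticoid-induced gene Tsc22d3 had a log2 change of -4.66 ± 1.09 (adjusted p = 0.00815, 6 of 6 below all controls), which lost its call with run as a term (adjusted p = 1.00) and without 99 (0.0549). The thioesterase Acot1 changed by 5.62 ± 1.28 (adjusted p = 0.00539), a call lost with run as a term (adjusted p = 1.00), without control 6 (0.0642) and without 102 (0.0848).

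By count, 14 of 4772 genes passed at 3.5 g/L (10 up, 4 down), 16 at 2 g/L (12 up, 4 down), 6 at 1 g/L (5 up, 1 down) and 17 for the trend (8 up, 9 down). At an unadjusted p under 0.05 there were 368, 226, 64 and 398. The count was 11 at 1 g/L without control 3 and 26 at 3.5 g/L without 97. The trend count was 10, 9, 8, 9, 8 and 8 without controls 3, 4, 5, 6, 7 and 8, 9 without 50, and 10 without each of 53, 73, 75, 78, 97 and 102. The median log2 change of all genes was -0.27, -0.67 and -0.68 at 1, 2 and 3.5 g/L with TMM scaling and 0.14, 0.02 and 0.07 with DESeq2 size factors, so changes here are relative to that shift. With the latter factors the counts split 19 up and 3 down at 3.5 g/L, 19 up and 3 down at 2 g/L, and 8 up and 2 down for the trend. Camera called 9 of 25 lists relative to all genes. Up were Cyp4 (adjusted p = 0.00127 with an estimated correlation), peroxisomal and other PPAR alpha genes (adjusted p = 0.0994 and 0.0994 with an estimated correlation), and mitochondrial fatty acid oxidation and fatty acid synthesis (adjusted p = 0.448 and 0.448 with an estimated correlation). Down were acute phase, unfolded protein response, hepatocyte secreted and red blood cell genes (adjusted p = 0.594, 0.448, 0.594 and 0.0723 with an estimated correlation). With DESeq2 size factors the first 3 of these were not called (adjusted p = 0.148, 0.0556 and 0.556), nor were unfolded protein genes with run as a term (0.1247) or acute phase genes without control 8 (0.163) or 97 (0.0753). Members passing were Ehhadh in the peroxisomal list, Cyp4a10 and Cyp4a14 among 10 in the Cyp4 list and 1 gene in the mitochondrial list, against 2, 3 and 1 adjusted over the list alone. The fatty acid synthesis list had a median of 0.12 and a mean of -0.004 (log2).

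Across the 2634 genes called in frozen liver at 3.5 g/L and tested in both preparations, r was 0.511 and rho 0.478 across genes, which are not independent replicates. The sign was shared by 60.0%, and 0.304% were also called in FFPE. Signs in FFPE are tilted by the median shift of -0.68 log2, and with DESeq2 size factors in both fits (median 0.07 in FFPE) 67.4% of 2637 genes shared their sign and r was 0.462. Leaving out animal 97 gave an r of 0.275, run as a term in the FFPE fit 0.303, DESeq2 fold changes 0.176 and thinned libraries 0.814. With different animals in each preparation, and thus fewer at 0 and 3.5 g/L in each fit, the median r was 0.413 over 36 divisions (0.162 to 0.529). The effect of 3.5 g/L differed between the preparations in 7 of 11526 genes (4 larger and 3 smaller in FFPE), namely Cyp4a14 (-4.60 ± 0.83, adjusted p = 9.09e-05), Brms1, Rn45s (not called without the animal as block, 0.52 log2, adjusted p = 0.770) and 4 unnamed genes listed by GenBank clone accessions, all 7 singled out after their values were seen. The median difference over all genes was -1.68 log2, the shift against which these values stand. With DESeq2 size factors, where it was -0.95, 11 genes passed (8 larger and 3 smaller in FFPE) and the values were -3.70 for Cyp4a14 and 4.26 for Rn45s. Without the animal as block 199 genes passed. Run and depth cannot be told apart from dose in FFPE at 3.5 g/L, so these differing effects cannot be assigned to DCA. Over 12 genes with a trend in both preparations, the median benchmark dose was 0.928 g/L in frozen and 1.21 g/L in FFPE (median ratio 1.60, quartiles 1.13 and 1.87). As for DEHP, the selection of genes by trend bounds both medians.

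Levels of many genes differed between FFPE and frozen tissue of the same animals. For both chemicals frozen tissue was of mixed lobes and FFPE tissue of specific lobes, so preparation and lobe cannot be told apart. In the DEHP animals Lars2, a mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123366927 to 123462666, plus strand, protein coding), was 5.80 ± 0.23 log2 higher in FFPE (n = 16 pairs), Rn45s 4.25 ± 0.18 and Xkrx 7.25 ± 0.28. Whether reads at Lars2 came from its own transcript or from ribosomal RNA was not tested. Lower were Mup10 (-4.07 ± 0.42, with reads shared among Mup genes), the ATP synthase subunit gene Atp5k (-1.22 ± 0.05) and the fatty acid binding protein Fabp4 (-1.17 ± 0.12), and Alb was lower by -0.70 ± 0.04. Of 13163 genes 8835 differed (4280 higher and 4555 lower in FFPE), 95.4% of them by less than 2-fold. The difference rose with GC content (Spearman 0.541 across genes) and less with length (0.221), and the median GC was 53.6% in higher and 45.2% in lower genes. Without the animal as block 7630 genes differed.

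In the DCA animals nearly all differing genes were lower in FFPE. Slirp, an RNA-binding protein of mitochondria, had a log2 difference of -5.88 ± 0.88, Rwdd1 -5.66 ± 0.82 and the mitochondrial ribosomal protein gene Mrpl11 -5.29 ± 0.83 (n = 24 pairs). H2-T22 had 0 counts in all FFPE libraries and was at least 158-fold lower, and Rrp15 had 1 FFPE count and was 181-fold lower (32.5 to 7158). Higher were counts at Lars2 (9.44 ± 0.20), the microRNA gene Mir6236 (7.76 ± 0.49), Rn45s (7.43 ± 0.12) and Ahdc1 (2.34 ± 0.45). Lars2 averaged 116500 CPM in FFPE against 71.7 CPM in frozen libraries, and Mir6236 178 against 1.235 CPM. Whether reads at Lars2 and Mir6236 came from their own transcripts or from ribosomal RNA was not tested, so higher expression of these genes is not shown. Of 10361 genes 6171 differed (43 higher, 6128 lower), and the median over all genes was -1.46 log2, the shift against which these values stand. The split was 283 higher and 1889 lower with DESeq2 size factors and 1156 and 1647 with the DESeq2 test, and 4053 genes differed without the animal as block.

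Both chemicals, an aromatic diester and a small chlorinated acid, raised fatty acid oxidation genes in frozen liver, and single genes of drug metabolism, cholesterol synthesis, the clock and macrophages differed in response. No list was tested as a whole for a difference. Their doses, routes, years and possibly durations differ, and each effect was taken against its own controls. Cyp2b10 rose with DEHP and was at -1.07 log2 with DCA (adjusted p = 0.132, none of 6 below all controls, 0.0460 without control 8 and 0.0253 without 97), a difference of 8.52 ± 1.16 (adjusted p = 6.89e-06). Cyp3a11 differed by 3.49 ± 0.53, Cyp2c29 by 2.32 ± 0.29 and Cd36 by 2.44 ± 0.50, all higher with DEHP. Cholesterol genes were higher with DEHP relative to DCA, with differences of 2.37 ± 0.37 for Hmgcs1, 2.03 ± 0.28 for Mvk and 1.97 ± 0.29 for Fdps, and 15 of the list's members differed, all in that direction. Cyp7a1 differed by -2.99 ± 0.66, Nr1d1 by -2.83 ± 0.51, Scd1 by -1.90 ± 0.45, Elovl6 by -1.82 ± 0.36 and Gbe1 by -1.39 ± 0.21, all higher with DCA. C1qa (1.33 ± 0.28) and Irf7 (1.31 ± 0.32) were lower with DCA, and 9 Kupffer cell genes differed that way.

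Among other leading genes, a difference was not shown for some and depended on single libraries for others. The 95% interval of the log2 difference was -0.55 to 1.61 for Ehhadh, -1.30 to 1.94 for Acot1 and -1.13 to 2.02 for Serpina12 (adjusted p = 0.554, 0.834 and 0.752), and that of Acot1 was 0.00588 without DEHP control 32A. For Cyp4a14 it was -4.46 to -0.47 (adjusted p = 0.0904, but 0.0263 without DEHP control 63A and 0.0321 without DCA control 4). Serpina1e fell less with DEHP, by a difference of 2.05 ± 0.57 (adjusted p = 0.0142, 0.0680 without 29B). For Lrtm1 and Tff3 the adjusted p was 0.0494 and 0.0424. The call of Lrtm1 was lost without DEHP controls 32A (0.0785), 45C (0.0769) or 75A (0.0914), 29B (0.102), 44A (0.121) or 64C (0.0740), and without DCA controls 4 (0.0585), 5 (0.0738) or 7 (0.0682), 97 (0.0828), 98 (0.0836), 100 (0.0710) or 102 (0.0686). That of Tff3 was lost without DEHP controls 32A (0.0805), 45C (0.0722) or 63A (0.0582), 29B (0.0978) or 44A (0.123), and without DCA controls 3 (0.0580), 5 (0.0518) or 8 (0.0767), 97 (0.0697), 98 (0.0652), 99 (0.0713) or 101 (0.0541). Of 13219 genes 1761 differed (856 higher and 905 lower with DEHP relative to DCA). Across 5934 genes called for either chemical r was 0.627 and rho 0.520, with genes not independent replicates, and 69.4% shared their sign. Both chemicals raised 565 genes against 202 expected of independent lists and lowered 359 against 133, and 76 were called in opposite directions against 333.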

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

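The tests of the 3 patterns weighed below were chosen after the data were seen, and those of Rn45s, of time of day and run for the clock genes and of the cell type markers also after their own values were seen. The sample comparisons and the splits were not.

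Cyp4a14, an omega-hydroxylase gene, and Rn45s, the ribosomal RNA precursor, differed between FFPE and frozen liver in their change at 3.5 g/L DCA by the edgeR test of the difference. In FFPE, run and depth cannot be told apart from dose at 3.5 g/L, so these differences cannot be assigned to DCA. The effect in FFPE minus that in frozen liver was -4.60 ± 0.83 log2 for Cyp4a14 (adjusted p = 9.09e-05) and 3.24 ± 0.26 for Rn45s (adjusted p = 7.01e-31). Without the replicate block that of Rn45s was 0.52 and not called (adjusted p = 0.770). The median difference over all genes was -1.68 log2, so part of the value of Cyp4a14 is a shift common to most genes, and with DESeq2 size factors (median -0.95) the values were -3.70 and 4.26. For Brms1, a repressor of metastasis, it was -14.24 ± 3.22 (adjusted p = 0.0159), a fitted value that rests on 142 frozen counts in 4 libraries at 3.5 g/L against 0 in controls, and 52 FFPE counts in 5 controls against 0 at 3.5 g/L.

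DEHP animal 29B had less of the drug-metabolising gene Cyp3a11 than the other animals at 6000 ppm. Its gap to the nearest animal was 0.939 of the group's range in frozen liver (log2 CPM 8.69, the others 12.10 to 12.32) and 0.865 in FFPE (7.28, the others 10.92 to 11.49), and its Cyp4a10 was apart in FFPE (0.864; 11.01 against 11.98 to 12.13). Cyp2b10 was detected in 1 frozen control, 45C (ratio 1), and Pdk4, a pyruvate dehydrogenase kinase gene, was high in FFPE control 32A (0.875). Among DCA animals Acot1, a thioesterase gene, was low in frozen 98 at 3.5 g/L (0.747) and high in FFPE control 4 (0.716). Pdk4 was high in frozen control 5 (0.711), Cyp2c55, an epoxygenase gene, low in frozen control 8 (0.660) and Gstz1 high in frozen control 7 (0.726).

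Rn45s took more of the counts than in the rest of the group in DEHP frozen 3A at 1500 ppm (0.488%, ratio 0.858), in DCA frozen control 3 (1.57%, ratio 0.691) and in DCA frozen 49 at 1 g/L (1.25%, ratio 0.920). Frozen library 101 at 3.5 g/L had more detected genes (16160, ratio 0.748), and FFPE library 97 at 3.5 g/L a higher total (ratio 0.680). Of 139 groups examined 15 had a sample apart by Dixon's ratio, and chance gives about 1 in 20.

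Few genes passed in FFPE liver of the DCA animals at 3.5 g/L. Frozen libraries thinned to the counts that Rn45s left in their FFPE partner still called 821 genes against 14. This argues against the number of counts, and the counts that Rn45s took, as the whole cause. Thinning matches counts but not the independent molecules behind them, so it cannot exclude that too few molecules were sequenced in FFPE. Deleting the Rn45s row gave 16 genes, but it gives back no reads and decides nothing. With run as a term 3 were called. A fall had been set beforehand as a sign against the run, but no run holds both dose groups and the run effect rests on 3 libraries against 3 at 1 g/L, so the run cannot be told apart from dose. Spread between FFPE animals was wide (biological coefficient of variation 1.16, against 0.144 in the thinned frozen libraries), and block age, which differs between the chemicals, may contribute and was not tested.

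Most clock genes moved in 2 opposite arms in frozen liver at 3.5 g/L DCA. The arm of Arntl, Npas2, Clock, Nfil3 and Cry1 fell by 0.90 log2 on average while the mean of Nr1d1, Dbp and 8 others rose, a difference of -2.40 (exact permutation p = 0.00216, the smallest possible over 924 divisions). At 2 g/L the difference was -1.16 (exact p = 0.00433), at 1 g/L 0.22 (exact p = 0.139). Against their arms, and singled out after the values were seen, Clock rose by 0.24 ± 0.06 and Per1 fell by 1.26 ± 0.37 (-2.28 at 1 g/L and -2.31 at 2 g/L), so a different time of day at collection is a candidate explanation that stays undecided. The libraries of both groups came from 1 run, in which 14 clock genes were called, and 12 of 14 were called in thinned libraries, which argues against run and depth. Lane cannot be told apart from dose, and an effect of DCA on the clock stays open and was not tested.

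Markers of Kupffer cells, the resident macrophages, and of red blood cells were lower in frozen liver at 3.5 g/L DCA. The Kupffer score (mean log2 CPM) moved by -0.25, -0.15 and -0.68 at 1, 2 and 3.5 g/L (exact permutation p = 0.0108, 0.394 and 0.00216), not in the order of dose, and that of red blood cells by -0.55, -1.08 and -1.18 (exact permutation p = 0.0628, 0.00649 and 0.00649). Kupffer minus endothelial markers moved by -0.47 log2 (exact permutation p = 0.00433), which argues against an equal loss of all other cell types. Within dose groups the slope of the Kupffer score on that of red blood cells was -0.10 (95% interval -0.36 to 0.16). Corrected with the upper limit of that slope, Kupffer markers were still lower by -0.48 (exact permutation p = 0.00216), which argues against less blood as the whole cause of their fall, as far as red blood cell genes follow blood. Less blood stays open for the red blood cell markers (below all controls in 4 of 6 libraries), since 1 lymphocyte gene could be tested. The Kupffer median with other scalings was no higher than -0.65 log2, which argues against scaling. Fewer Kupffer cells, or lower expression within them, may each account for it and were not separated.

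Random divisions of the libraries were used to ask whether chance can be excluded. For DEHP in frozen liver it can at 1500 ppm (895 genes, highest other 7), 3000 ppm (2022 and 21) and 6000 ppm (1625 and 540), the real one being the 1 division of 35 with a count as large, and for the trend (360 and 291, 100 divisions). In DEHP FFPE it can as well (796 and 2, 1275 and 9, 1680 and 271 of 35, trend 487 and 214 of 100). Both DEHP trend counts were unstable on leaving out 1 library (57 to 1266 in frozen, 49 to 1028 in FFPE). For the DEHP trends the exclusion is thus weak. Chance can be excluded for DCA frozen (1455 and 11, 3822 and 554, 5631 and 2548 of 60, trend 5141 and 2 of 100), and for DCA FFPE at 2 g/L (16 and 7), 3.5 g/L (14 and 8) and the trend (17 and 4). At 1 g/L in DCA FFPE it cannot, since 10 of 100 divisions gave 6 genes or more (highest 11). It can for FFPE against frozen (DEHP 8835 and 5194 of 60, DCA 6171 and 7 of 28) and for DEHP against DCA (1761 and 421 of 40). The differing effects in DCA gave 7 genes, against 5 in the highest other of 21 divisions. So few divisions and so small a gap do not firmly exclude chance there. For the differing effects in DEHP the real count was 0 (highest other 1), which all 35 divisions reach by construction, so they decide nothing. For the number of lists called chance cannot be excluded: 3 of 35 divisions reached 18 in DEHP frozen (highest other 19), 5 of 35 reached 17 in DEHP FFPE (18), 5 of 60 reached 19 in DCA frozen (20) and 5 of 100 reached 9 in DCA FFPE (10).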

How the results depend on the processing

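Run as a term, fits without the Rn45s row, without selected libraries or within 1 run, DESeq2 size factors for r between preparations, and leaving out animals in turn for DEHP FFPE against frozen, for differing effects in DEHP and for DEHP against DCA, were chosen after seeing the data. The other alternatives were planned. Upper-quartile factors could not be run for DCA FFPE, where the upper quartile of a library is 0.

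Named genes kept their direction wherever they were called in the main fit or in the alternative. Of 8778 comparisons of a named gene with an alternative, 8440 stayed called or stayed not called, 286 lost the call, 52 gained it and none changed sign while called. Genes called in neither fit were not checked for a change of sign. For lists 1514 of 1652 stayed, 101 lost and 35 gained a call, and 2 reversed. These were mitochondrial fatty acid oxidation and ketogenesis, and fatty acid and triglyceride synthesis, in DCA FFPE, where fry, a rotation test in limma that does not compare a list with the other genes, gave the other direction (adjusted p by rotation 0.713 and 0.636, not called). With an estimated correlation 4 lists were called in DEHP frozen, 4 in DEHP FFPE, 0 in DCA frozen (camera in limma, 8 at an unadjusted p under 0.05, 23 with fry) and 1 in DCA FFPE.

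Stricter thresholds gave fewer genes by construction. An adjusted p under 0.01 gave 257, 812 and 679 genes in DEHP frozen at 1500, 3000 and 6000 ppm, 235, 543 and 667 in DEHP FFPE, and 345 and 2308 in DCA frozen at 1 and 2 g/L. A change of at least 2-fold gave 318, 611 and 527, then 303, 486 and 543, and 132, 512 and 793 in DCA frozen.

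The DESeq2 test gave 915 and 1108 genes for the DEHP trend in frozen and FFPE, 25, 36 and 40 in DCA FFPE at 2 g/L, 3.5 g/L and the trend, and 2803 for FFPE against frozen with the replicate block. With DESeq2 fold changes r between preparations was 0.881 for DEHP and 0.176 for DCA. DESeq2 size factors gave 10, 22 and 10 genes in DCA FFPE at 1 g/L, 3.5 g/L and the trend, 2172 for DCA FFPE against frozen and 11 for differing effects. For these and the following values, the cause was not tested unless it is named.

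Without the replicate block, the pairing of animals left aside, 4053 genes differed between DCA FFPE and frozen and 199 in their effect. Over all genes r was 0.856 for DEHP preparations and 0.555 between the chemicals. With different animals in each preparation, and thus fewer in each fit, the median r for DEHP was 0.878, over genes called in frozen liver rather than all genes. Dose rank in place of dose gave 1031 and 1100 genes with a DEHP trend. Genes with a trend in frozen liver alone gave a DEHP benchmark ratio of 1.10.

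Thinning to the smallest total gave 38, 371 and 460 genes in DCA frozen at 1, 2 and 3.5 g/L, 406 for DCA FFPE against frozen, and r = 0.814 for DCA, through lower depth and fewer genes tested. Without a filter 1 gene had a differing effect in DEHP, and DCA FFPE gave 13 at 1 g/L, 27 at 3.5 g/L and 992 for the trend. The stricter filter gave 13 and 9 in DCA FFPE at 1 and 2 g/L. Fits of the compared groups alone, with fewer samples, gave 1029 for DEHP frozen at 6000 ppm and 784 and 904 for FFPE at 3000 and 6000 ppm.

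With run as a term there were 391, 561 and 667 genes in DEHP frozen, 513 in DEHP FFPE at 1500 ppm, 510 in DCA frozen at 1 g/L, and 4 and 3 in DCA FFPE at 2 and 3.5 g/L, with r = 0.303 for DCA. Within run V18431, edgeR called 0 genes at 1 g/L in DCA FFPE (982 at an unadjusted p under 0.05). The other deposited tables gave 525 in DEHP frozen at 1500 ppm, and 7 and 9 in DCA FFPE at 2 and 3.5 g/L. Without the 3 lowest totals DCA frozen at 2 g/L gave 2377, and without 40A DEHP frozen at 1500 ppm gave 494.

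Leaving out each library in turn gave, in DEHP frozen, 445 to 1181 genes at 1500 ppm, 1246 to 2178 at 3000 ppm, 903 to 2041 at 6000 ppm, 57 to 1266 for the trend and 16 to 19 lists. At 1500 ppm the count was 468 without control 45C, 480 without control 63A, 493 without control 75A, 494 without 40A and 445 without 60A. At 3000 ppm it was 1246 without control 63A, 1327 without 67C and 1322 without 9A, and at 6000 ppm 1079 without control 63A, 921 without 44A and 903 without 8C. For the trend it was 119, 159, 110 and 163 without controls 32A, 45C, 63A and 75A, and 1266, 57, 232 and 105 without 29B, 44A, 64C and 8C.

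In DEHP FFPE the ranges were 367 to 983, 846 to 1384, 856 to 1951, 49 to 1028 for the trend and 13 to 19 lists. At 1500 ppm the count was 449, 458 and 423 without controls 45C, 63A and 75A, and 461, 367, 434 and 518 without 3A, 40A, 60A and 72B. At 3000 ppm it was 846 without control 63A, and at 6000 ppm 856 without 44A and 1078 without 64C. For the trend it was 117, 223, 119 and 210 without controls 32A, 45C, 63A and 75A, and 1028, 49 and 218 without 29B, 44A and 64C.

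In DCA frozen the ranges were 863 to 2317 at 1 g/L, 3396 to 4009 at 2 g/L, 5001 to 5545 at 3.5 g/L, 4673 to 5223 for the trend and 17 to 21 lists. At 1 g/L the count was 863 without control 3, and 2317, 870, 960 and 899 without 49, 51, 52 and 54. In DCA FFPE they were 4 to 11, 12 to 18, 12 to 26, 8 to 17 for the trend and 8 to 10 lists. The count was 11 at 1 g/L without control 3 and 26 at 3.5 g/L without 97. The trend count was 10, 9, 8, 9, 8 and 8 without controls 3, 4, 5, 6, 7 and 8, 9 without 50, and 10 without each of 53, 73, 75, 78, 97 and 102.

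FFPE against frozen gave 8537 to 8870 genes in DEHP. The test of differing effects gave 0 to 0 in DEHP (edgeR, 254 at an unadjusted p under 0.05 with all animals). The difference between chemicals gave 1271 to 1838 genes. The r between preparations was 0.955 to 0.974 for DEHP and 0.275 to 0.4997 for DCA, lowest without 97, and r between chemicals 0.607 to 0.651. Benchmark ratios were 0.998 to 1.07 for DEHP and 1.47 to 1.78 for DCA. Depth limits what can be seen in part, since frozen DCA libraries thinned to the counts of their FFPE partners had 821 of 4623 genes called against 5631 of 13089.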

Other observations

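The tests of block labels were chosen after the values were seen. Cyp4a14, the omega-hydroxylase gene, was high in FFPE tissue of some DCA animals at 1 g/L whose frozen tissue had little of it. In FFPE libraries 49, 51 and 54 it was at 265, 571 and 700 CPM, and in their frozen partners at 3.45, 14.8 and 29.4 CPM. The other FFPE libraries at 1 g/L, 50, 52 and 53, were at 7.54, 58.98 and 9.93 CPM, with frozen partners at 3.49, 15.3 and 7.65 CPM. Control 3 was at 76.1 CPM in FFPE and 5.46 CPM in frozen liver. Libraries 49 and 51 were in run V18431 and 54 in run W48315. Cyp4a10 went the same way (47.0, 270 and 417 CPM in FFPE 49, 51 and 54, against 5.98, 35.99 and 59.7 CPM frozen), as did Ehhadh (177, 655 and 977 CPM in FFPE, against 174, 237 and 239 CPM frozen), which was lower in FFPE controls (31.5 to 87.4 CPM) than in frozen controls (133 to 196 CPM).

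A wrong label would change what the FFPE values at 1 g/L and the animal pairs mean. An exchange with blocks at 2 or 3.5 g/L would leave blocks with low values there, but the lowest mean log2 CPM of the 3 genes in those 12 FFPE libraries was 8.29, above the highest control (5.64), which argues against it. A wrong label without such an exchange cannot be told apart from other causes by the pairing. Frozen and FFPE residuals of 49, 51 and 54 correlated at 0.00512, 0.00661 and 0.0376, and those of 52 and 53, without high values, at 0.0189 and 0.0377, and none of these 5 animals matched its own partner best. Animal 50 did (0.179). A difference between the lobes sampled was not tested.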
